A study of Mus musculus with 16 samples.

How the data were processed

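Lineage-negative, Kit-positive cells of mice at 14 days of age were measured in 16 libraries. The method, per the labels' protocols, was 10x Genomics 3' version 3.1 single-cell RNA sequencing with antibody tags. No set of libraries held a second library of a genotype, but wildtype and WT, in different sets, were both unmutated by label. The deposited values are whole-number UMI counts per gene or antibody and cell barcode, with 32285 genes per library and 10 antibody tags shared by all libraries (16 in the set of 4 labelled WT, ITDvav, NHD13 and NHD13ITDVav). Cell Ranger 6.0.1 and the mm10 build are named in the submitters' processing notes; filters beyond Cell Ranger's own, and doublet removal, are not given in the sources used here. Of the genes, 32158 were matched by identifier to GENCODE M21 on mm10 for their positions. Neither Mx1 nor Mx2 was found under those symbols, and they were not used here.

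Barcodes with at least 500 genes and under 10% mitochondrial counts were kept. Doublets were scored per library against simulated pairs of cells, and the highest scores were removed at 0.8% per 1000 cells (1.56% to 7.86% per library). Of 115626 barcodes 90734 remained. The share of barcodes over the mitochondrial limit ran from 4.60% to 42.0% per library, highest in NUP98-HOXD13 Ifnar+/-. Median UMIs per kept cell ran from 12927 to 48091. Deposited antibody counts of the 10 shared tags ran from 7595425 to 42668636 per library.

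Cells were clustered jointly. The 2000 most variable genes were taken within libraries, leaving out interferon response, MHC class I, cell cycle, mitochondrial, ribosomal protein and Y-linked genes, Xist and Tsix. Each set was centred on its library with none of the tested factors, which was Ifnar+/-, wildtype or WT. Then 30 principal components and 20 neighbours were used, up to 1500 cells per library were clustered by Leiden at resolution 1 (leidenalg 0.10.2), and other cells took the commonest cluster of their 15 nearest neighbours. Of 22 clusters 17 were named from marker genes fixed before the data were examined. A rule added after the data were seen, that a cluster with none of its own markers among its 10 leading genes stays unnamed, left out 4 clusters; 1 more had under 3 markers. The share of unnamed clusters per library is plotted beside the named classes. Clusters 9, 14 and 15 were over 98% of 1 library each (NHD13ITDVav, ITDvav and NHD13) and may be those libraries and not a cell type. Class names are rebuilt here and may differ from those of the study's authors.

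Counts were summed per library over all kept cells and, where a library had at least 30 cells, within classes. Libraries were paired by the labels' factors within a set, since no set held a second library of a genotype. Across sets, wildtype and WT were alike in their factors, as were Flt3-ITD and ITDvav as pooled here, but each was paired only within its set. The design was fixed before the data were examined: edgeR 4.0.16 quasi-likelihood tests with TMM scaling, edgeR's filter on low counts, a block per pair or square, and Benjamini-Hochberg adjustment at 0.05. Runx1-het and the interactions of the ITD with Runx1-het and with Ifnar-/- came from 1 model of all 16 libraries with 5 residual degrees of freedom. The title "Runx1-et" was read as Runx1-het. ITDvav and NHD13ITDVav were counted as carrying the ITD and pooled with the Flt3-ITD libraries; the labels do not say whether the allele, or what drives it, differs between them. Nothing in the labels says how many animals made up a library, so p-values measure only the spread between libraries. In 5 libraries both Xist and Ddx3y were counted, as a pool of animals of both sexes would give, but the number of animals stays unknown. Fold changes are of summed counts, so they hold changes in the mix of cells. Genes with near-identical copies, such as the H2-Q genes, the alpha globins and the histone genes, are uncertain because reads may be divided between copies.

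Genes were named by a rule fixed beforehand: for the ITD, NUP98-HOXD13 and Ifnar-/- up to 8 rising and 8 falling genes with the largest log2 change among those past the threshold, with 1 sign in every pair and a mean of at least 20 CPM, and up to 3 genes from each of 27 gene lists; for other fits up to 5 in each direction; and the label genes. Predicted genes, antigen receptor segments, Y-linked genes, Xist and Tsix were left out. Exceptions chosen after their values were seen are Eif2s3y, the sex-linked genes Xist and Ddx3y used to describe the libraries, the levels of Camp, Ngp, S100a8 and S100a9 beside Runx1-het, and the Dlk1, Igf1 and Isg15 values per library in the closing section. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry (limma 3.58.1), which asks whether a list's genes move 1 way on balance and compares them with no others. Of 100 camera calls over the 7 all-cell comparisons, 1 held with an estimated correlation. Fry called 14 of 27 lists for the ITD, 10 of 27 for NUP98-HOXD13 and 0 in each other all-cell comparison. With 7682 of 16199 genes called for the ITD, a fry call does not set a list apart from other genes. List levels per library are mean log2 CPM of library totals with a prior count of 2; summed CPM was computed beside it. Medians of lists that hold genes at 0 counts on 1 side did not change with those genes set to their bound of 3 counts over the group.

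Class shares were compared by two-sided exact sign-flip permutation tests of the logit share difference per pair with 0.5 cells added, and antibodies by the same test on log2 shares of the 10 tags' counts and, as an alternative added after the data were seen, on log2 counts per kept cell. Exact binomial 95% intervals of shares, and the floor of 3 counts for a count of 0, cover counting error only.

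The tests were tried on simulated counts drawn from each gene's real mean, the real library sizes and a dispersion trend, with 200 genes changed. For the ITD fit (16199 genes) 56.7%, 85.1% and 95.5% of genes changed 1.5-fold, 2-fold and 4-fold were called, and 4.82% of calls were false. For NUP98-HOXD13 (16000 genes) the shares were 50.7%, 71.6% and 95.5%, for Ifnar-/- (15463 genes) 74.6%, 80.6% and 98.5%, and for Runx1-het (16805 genes) 0%, 38.8% and 84.8%. A simulated gene changed by the same fold in every pair. Real changes may differ between backgrounds, so these shares can overstate how many real changes the tests would call. The real ITD fit called 7682 genes, far more than the 200 changed here, so the simulated share of false calls need not hold for it.

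Alternatives fixed beforehand were DESeq2 1.42.0 size factors, DESeq2's Wald test, no filter on low counts, cells with at least 1000 genes and under 5% mitochondrial counts, doublets kept, additive factors in place of the block, the set of 4 with WT left out, each pair left out in turn, Leiden resolution 2 and no centring of sets. Added after the data were seen were the counts without 3 clusters of low UMI, counts within the erythroid-like class, fits without the Ifnar-/- libraries, the NUP98-HOXD13 by Ifnar-/- interaction, counts of calls without sex-linked genes, and the share of all-cell ITD calls with the same sign within a class under swapped labels. For the last, genes were ranked by the mean over the SD of their pair differences and as many were taken as there were calls. Analyses ran in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1) and R 4.3.3.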

Results

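Lineage-negative, Kit-positive blood progenitor cells of 14-day-old mice were profiled by droplet single-cell RNA sequencing with antibody tags (CITE-seq), with 16 libraries in all. The genotypes combined 4 factors: an internal tandem duplication in the receptor tyrosine kinase gene Flt3 (ITD), a mutation found in acute myeloid leukaemia; the fusion gene NUP98-HOXD13; loss of 1 copy of Runx1, a blood transcription factor; and loss of the type I interferon receptor, labelled Ifnar-/-. By their labels the libraries fell into a set of 8 crossing the ITD, NUP98-HOXD13 and Ifnar, a set of 4 crossing the ITD and Runx1-het, and a set of 4 labelled WT, ITDvav, NHD13 and NHD13ITDVav. In the set of 8 the libraries that were not Ifnar-/- were Ifnar+/-, which by label keeps 1 receptor copy. Ifnar-/- was therefore compared with loss of 1 copy and not with the intact receptor. The labels do not say whether the ITD of ITDvav and NHD13ITDVav is the same allele as that of the libraries labelled Flt3-ITD, and both were counted as 1 factor. Within a set every genotype had 1 library, and the libraries labelled wildtype and WT were both unmutated but lay in different sets. The replicates of each comparison were therefore pairs of libraries that differed in the tested factor and shared the other labels: 8 pairs for the ITD, 6 for NUP98-HOXD13, 4 for Ifnar-/- and 2 for Runx1-het. After filtering, 90734 cells remained, from 1896 to 9056 per library, with 78424241 to 175215654 unique molecular identifiers (UMIs) per library. Whether a set was also a sequencing batch is not given in the labels, and every pair lay within 1 set.

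The genes named in the labels were examined first. Hoxd13 had 97 counts in the 6 libraries labelled with NUP98-HOXD13 and 0 in their 6 partners, a difference of at least 28.2-fold against a floor of 3 counts over the partners. Runx1 was not lower with the Runx1-het label: 117 CPM (counts scaled to library size) in Runx1-het against 95.4 in wildtype, and 221 in Flt3-ITD Runx1-het against 125 in Flt3-ITD. Ifnar1 and Ifnar2 had log2 differences of -0.13 ± 0.07 (SE, n = 4 pairs) and 0.00 ± 0.05 with the Ifnar-/- label. The 3' tags counted here may lie outside the deleted parts of Runx1 and Ifnar1 or Ifnar2, so their levels check neither label. Runx1 itself rose with the ITD by 0.66 ± 0.09 (SE, n = 8 pairs, edgeR adjusted p = 0.0018). Flt3 counts do not separate the duplicated allele from the normal one. The libraries also differed in sex. Xist, transcribed from the inactive X chromosome of female cells, was at 0.0626 to 0.21 CPM in Flt3-ITD, Flt3-ITD Ifnar-/-, Ifnar-/- and WT, where the Y-linked gene Ddx3y was at 39.9 to 45.5. The 4 Ifnar+/- libraries and Flt3-ITD NUP98-HOXD13 Ifnar-/- had both, with Xist at 569.5 to 771 and Ddx3y at 21.04 to 25.9, and the other 7 had Xist at 897 to 1372 and no Ddx3y count. These genes were alike in 5 of the 8 ITD pairs, 3 of the 6 NUP98-HOXD13 pairs, 1 of the 4 Ifnar-/- pairs and 1 of the 2 Runx1-het pairs, and no Y-linked gene, Xist or Tsix passed in an all-cell comparison.

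The first comparison asked what the ITD changed across backgrounds. Socs2, a feedback inhibitor of cytokine signalling induced by STAT5, rose 18.2-fold (log2 4.19 ± 0.28 SE, n = 8 pairs, edgeR adjusted p = 0.000167), higher in 8 of 8 pairs. Ifitm1, an interferon-inducible membrane protein also high in stem cells, rose 13.7-fold (log2 3.77 ± 0.20), and the invariant chain gene Cd74 rose 9.07-fold (log2 3.18 ± 0.52). Ccnd1, which encodes cyclin D1, fell by 2.44 ± 0.32 on the log2 scale, from a mean of 55.7 to 12.3 CPM. Other genes with the largest changes that shared a sign in every pair were Myl10 (3.53 ± 0.42), S100a4 (2.50 ± 0.35), S100a6 (1.88 ± 0.37), Serpina3g (1.76 ± 0.15) and Mycn (1.57 ± 0.13) among those that rose, and Sphk1 (-1.76 ± 0.58), Slc38a5 (-1.68 ± 0.58), Ermap (-1.59 ± 0.56), Rhd (-1.58 ± 0.58), Tmem56 (-1.58 ± 0.53), Add2 (-1.56 ± 0.56) and Hba-a1 (-1.55 ± 0.35) among those that fell. Socs2 lies on chromosome 10 at 95385362 to 95417180 on the minus strand of mm10, a protein-coding gene in the annotation, and Ccnd1 on chromosome 7 at 144929931 to 144939925, also on the minus strand.

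Targets of STAT5, the transcription factor downstream of many cytokine receptors, moved with Socs2. Of 14 measured, 11 rose and 3 did not pass the test (12 rose and 2 fell adjusted over the list alone), with Il2ra at 5.41 ± 0.99 and Cish at 1.99 ± 0.15 on the log2 scale. Their camera test gave adjusted p = 6.4e-09, and adjusted p = 0.058 with an estimated correlation. Feedback genes of the MAPK pathway went the other way, with 10 of 14 falling and 1 rising, the same counts adjusted over the list alone. Etv4 (-2.21 ± 0.46) and Spry4 (-1.95 ± 0.40) fell and Dusp5, a phosphatase of the same group, rose (1.81 ± 0.21). That list's camera call (adjusted p = 0.0028) had adjusted p = 0.5256 with an estimated correlation.

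Antiviral genes of the type I interferon response rose with the ITD: 48 of 64 rose, none fell and 16 did not pass (51 rose adjusted over the list alone), with a median log2 change of 0.87. Slfn2 (2.74 ± 0.29) and Ifit3b (2.51 ± 0.78) were among the largest; Slfn1 had 139 counts with the ITD and 0 without. The list's camera test had adjusted p = 2.12e-13, and adjusted p = 0.5256 with an estimated correlation. The medians of single pairs ran from -0.09 in the Runx1-het pair, where 26 of 64 members were above 0, to 1.93 in the pair of NHD13ITDVav and NHD13. Of 16 genes of MHC class I antigen presentation, 14 rose (15 adjusted over the list alone), led by H2-Q6 (1.31 ± 0.19) and H2-Q7 (0.86 ± 0.12), near-identical copies between which reads may be divided. Of 8 MHC class II genes, 7 rose (7 adjusted over the list alone), including H2-Aa (3.17 ± 0.47). Cd74 was highest in ITDvav (234 CPM) and Flt3-ITD Runx1-het (115), the libraries with most dendritic-like cells (1.77% and 1.19%, against at most 0.139% in any other). Within HSC/MPP-like cells the class II list had a median of -0.21 with 0 of 7 passing (1 rose adjusted over the list alone), and within erythroid-like cells 0.30 with 2 of 8 rising. Both MHC lists had adjusted p = 0.446 with an estimated correlation.

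**Figure D1:**
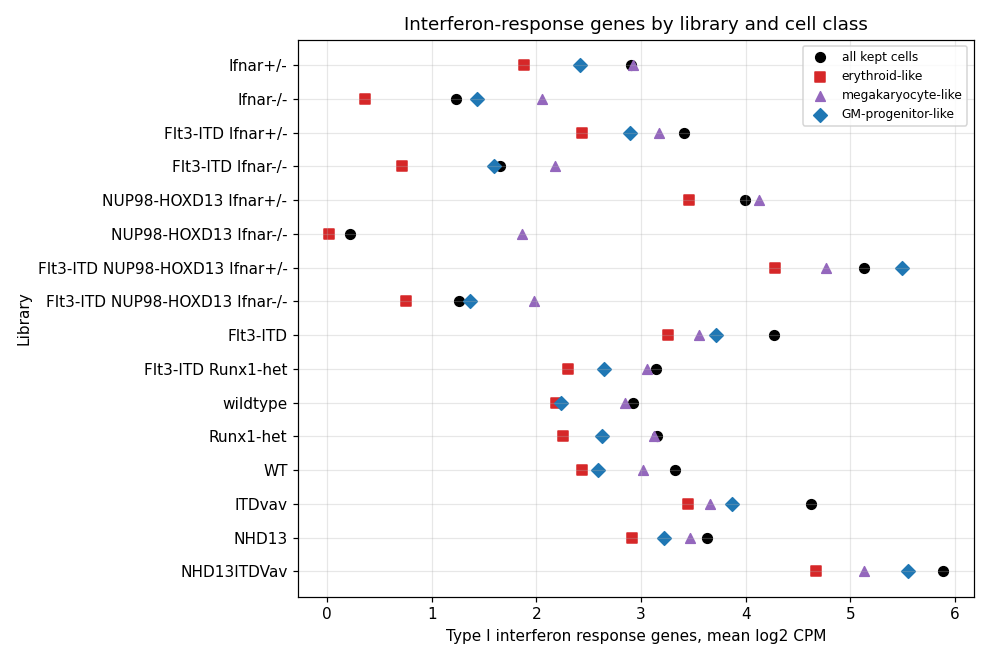
Mean log2 CPM of the type I interferon response genes (horizontal axis) in each of the 16 libraries (vertical axis), over all kept cells and within 3 cell classes, with points only where a class held at least 30 cells. Over all kept cells the values run from 0.22 in NUP98-HOXD13 Ifnar-/- to 5.88 in NHD13ITDVav.

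Among cell type genes, the erythroid list fell with the ITD: 13 of 18 fell and 5 did not pass (16 fell adjusted over the list alone), with a median of -1.43 and the alpha globin gene Hba-a2 at -1.62 ± 0.34. Its camera call (adjusted p = 8.16e-06) had adjusted p = 0.5256 with an estimated correlation. The erythroid-like share of cells was lower with the ITD in 8 of 8 pairs beside this change, and these all-cell values hold both. Counts summed within the erythroid-like class gave the erythroid list a median of -0.23, with 5 of 18 falling. In NHD13 most of that class was cluster 15 (41.1% of the library, of 48.3% in the class), which held at most 0.574% of any other library. Monocyte genes rose (10 of 13, the same 10 adjusted over the list alone; Irf8 1.25 ± 0.16, Ctss 1.31 ± 0.24), as did 7 of 14 granulocyte-monocyte progenitor genes (7 adjusted over the list alone; Cebpa 0.71 ± 0.18, Lyz2 0.80 ± 0.15), 6 of 11 dendritic cell genes with 1 falling (Clec9a 3.14 ± 0.63) and 13 of 20 genes of haematopoietic stem cells with 1 falling (Ly6a 1.31 ± 0.39). With an estimated correlation these 4 lists had adjusted p = 0.446, 0.682, 0.446 and 0.446. Ly6a also fell with the Ifnar-/- label within HSC/MPP-like cells (-1.03 ± 0.09 SE, n = 2 pairs), so its rise need not reflect stem cells. Genes of dividing cells fell by small amounts, 46 of 52 for the G2 and M phases (47 adjusted over the list alone; Cenpa -0.60 ± 0.08) and 27 of 42 for S phase with 2 rising (31 fell and 2 rose adjusted over the list alone; Cdc6 -0.38 ± 0.06). Of 15 genes of MYC targets and ribosome assembly 14 fell (15 adjusted over the list alone; Nolc1 -0.38 ± 0.06). With an estimated correlation the adjusted p were 0.46, 0.576 and 0.446 for these lists. The medians of the G2 and M, S phase and MYC lists were -0.31, -0.16 and -0.33 over all cells and -0.24, -0.15 and -0.19 within GM-progenitor-like cells. Within HSC/MPP-like cells they had the opposite sign, at 0.05, 0.12 and 0.16, with no member passing (1 MYC list member rose adjusted over the list alone).

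Of the other fixed lists, megakaryocyte genes had 6 of 14 rising and 1 falling, HOX genes 6 of 20 rising, p53 targets 4 of 14 rising and 4 falling, and proinflammatory genes 4 of 12 rising and 1 falling, and no camera test of these lists passed (adjusted p from 0.139 to 0.877).

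In all, genes changed by ITD numbered 3855 rising and 3827 falling of 16199, of which 2490 and 2874 had 1 sign in all 8 pairs. Because the libraries are of 1 mouse genotype each, the p-values measure how steady the ITD difference was across backgrounds, and within a set nothing separates a genotype from its single library. Counts summed within the erythroid-like class alone, an alternative added after the data were seen, gave 1648 genes, with cluster 15 as most of the class in NHD13. Without the set that holds ITDvav and NHD13ITDVav the all-cell count was 6270, of which 5936 were among the 7682.

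Within the GM-progenitor-like class, cells that carry the granule enzymes Mpo and Elane, 367 of 12290 genes rose and 115 fell with the ITD in 6 pairs. Socs2 rose 82.6-fold (log2 6.37 ± 0.15, edgeR adjusted p = 5.59e-10) and Ifitm1 9.78-fold (3.29 ± 0.19), with Ifitm3 (1.29 ± 0.16), Serpina3g (1.26 ± 0.08) and the guanylate-binding protein gene Gbp7 (1.05 ± 0.12) also higher in 6 of 6 pairs. Ccnd1 fell by 3.35 ± 0.27 on the log2 scale, the calgranulin gene S100a8 by 2.71 ± 0.46, Trem3 by 1.02 ± 0.18, the transferrin receptor gene Tfrc by 0.84 ± 0.21 and Lmo1 by 0.78 ± 0.13. Interferon response genes rose here in 31 of 61 cases (56 adjusted over the list alone), and 4 of 13 STAT5 targets rose. The STAT5 list kept its camera call with an estimated correlation (adjusted p = 0.00735), and the interferon list had adjusted p = 0.378 with an estimated correlation. Without the pair of ITDvav and WT the count of changed genes was 129, and with that of Flt3-ITD Runx1-het, Flt3-ITD or Flt3-ITD Ifnar-/- left out it was 236, 242 or 266.

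In the HSC/MPP-like class, named for stem cell genes such as Hlf and Mecom, 57 of 11624 genes rose and 26 fell with the ITD in 5 pairs. Socs2 (2.35 ± 0.10), Ifitm1 (1.78 ± 0.11), the actin regulator gene Enah (3.33 ± 0.28), Cd48, a surface marker low on the most primitive cells (1.96 ± 0.28), and Myl10 (1.84 ± 0.20) rose in 5 of 5 pairs. Ccnd1 (-3.07 ± 0.46), Rgs1 (-2.44 ± 0.31), Tnip3 (-2.34 ± 0.35), the immediate early gene Egr1 (-1.65 ± 0.15) and Hbb-bt (-1.56 ± 0.29) fell in 5 of 5. Of 19 stem cell genes 1 rose and none fell (1 rose and 8 fell adjusted over the list alone), with a median of -0.56, the opposite sign to that over all cells; the camera call (adjusted p = 5.21e-06) had adjusted p = 0.389 with an estimated correlation. The class was held by cluster 14 in ITDvav and by cluster 10 in the other libraries, and without the pair of ITDvav and WT the count was 289. It was 20 to 49 when any other pair was left out: 49 for Flt3-ITD Ifnar+/-, 31 for Flt3-ITD Ifnar-/-, 21 for Flt3-ITD and 20 for Flt3-ITD Runx1-het.

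The second comparison asked what NUP98-HOXD13 changed. Genes of the HOX clusters and their cofactors, which set progenitor identity, changed in all 20 measured cases: 17 rose and 3 fell, the same counts adjusted over the list alone. Hoxb8 rose by 11.41 ± 0.21 on the log2 scale (n = 6 pairs, edgeR adjusted p = 6.38e-07), from 0.0119 to 32.5 CPM, and Hoxc4 by 11.19 ± 0.35. Hoxc5 had 8315 counts with the fusion and 2 without. Pbx3, a HOX cofactor gene of the list, rose 13.9-fold (3.80 ± 0.19), and Hoxa7, also of the list, by 1.42 ± 0.06. Outside that list, Lin28b, an RNA-binding protein of fetal progenitors, rose 19.8-fold (4.31 ± 0.24) and Hopx 9.99-fold (3.32 ± 0.44), each higher in 6 of 6 pairs. Isg15 (2.76 ± 0.49), Eya1 (1.67 ± 0.10), the amino acid transporter gene Slc7a5 (1.66 ± 0.26) and Pcdh7 (1.40 ± 0.18) also rose in 6 of 6. The HOX list kept its camera call with an estimated correlation (adjusted p = 0.00653). Hoxb8 lies on chromosome 11 at 96281905 to 96285315 on the plus strand of mm10, and Lin28b on chromosome 10 at 45376620 to 45486395 on the minus strand.

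Of 14 granulocyte-monocyte progenitor genes 12 fell with NUP98-HOXD13 (13 adjusted over the list alone), with the neutrophil elastase gene Elane at -2.82 ± 0.48 and Nkg7 at -2.32 ± 0.26. Of 13 monocyte genes 8 fell (8 adjusted over the list alone; Csf1r -2.65 ± 0.36, Ccr2 -2.28 ± 0.48, Irf8 -2.23 ± 0.45), of 8 MHC class II genes 5 fell (5 adjusted over the list alone; Cd74 -3.09 ± 0.30, H2-Aa -3.63 ± 0.44) and of 20 stem cell genes 8 fell and 1 rose (the same adjusted over the list alone; Robo4 -4.38 ± 0.43, Esam -4.05 ± 0.24, with Hoxb5 rising by 4.86 ± 0.33). With an estimated correlation these lists had adjusted p = 0.5678, 0.5678, 0.452 and 0.5678. Within GM-progenitor-like cells, tested in 4 pairs, their medians were nearer 0 or of the opposite sign. The granulocyte-monocyte progenitor list had a median of -0.15 there against -1.76 over all cells, with 2 of 14 falling (4 adjusted over the list alone), and the monocyte list -0.30 against -1.47, with 2 of 12 falling (2 adjusted over the list alone). Stem cell genes had 0.40 against -1.06, with 2 of 15 rising and 1 falling (2 rose and 2 fell adjusted over the list alone). Dntt, which adds nucleotides to rearranging antigen receptors, fell by 3.62 ± 0.36, and Cd34 (-2.19 ± 0.34), Ltb (-2.43 ± 0.50), Ifitm1 (-2.87 ± 0.59) and Basp1 (-2.06 ± 0.33) were lower in 6 of 6 pairs. All 5 genes of stroma and endothelium fell (5 adjusted over the list alone; Kdr -1.97 ± 0.22), with adjusted p = 0.339 with an estimated correlation. In other lists fewer members passed. Of 10 neutrophil genes 2 fell (Cebpe -1.79 ± 0.38), of 12 T and NK lineage genes 2, of 15 lymphoid-primed genes 2 and of 11 proinflammatory genes 4 (2, 1, 1 and 4 adjusted over the list alone), with adjusted p = 0.647, 0.761, 0.761 and 0.668 with an estimated correlation. The pair of NHD13ITDVav and ITDvav went the other way in T and NK lineage genes, with a median of 4.55 (nearest other -1.93), and in lymphoid-primed genes, with 1.43 against -2.77 to -1.05 in the other 5 pairs, that of NHD13 and WT included. T/NK-lineage-like cells made up 9.15% of NHD13ITDVav and at most 0.692% of any other library, although the cells were sorted as lineage-negative and Kit-positive, a gate meant to remove T and NK cells. These falls stand beside lower shares of HSC/MPP-like, lymphoid-primed-like and GM-progenitor-like cells in 6 of 6 pairs. Barcodes over the mitochondrial limit were 42.0%, 30.5%, 32.2% and 23.6% in the fusion libraries of the Ifnar set against 22.5%, 26.6%, 16.3% and 14.0% in their partners. They were 9.23% in NHD13 against 5.55% in WT, and 4.60% in NHD13ITDVav against 6.05% in ITDvav. With stricter cell filters 4286 of the 4770 genes changed by NUP98-HOXD13 were called again.

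Of 15 MYC target and ribosome assembly genes 8 rose with NUP98-HOXD13 (14 adjusted over the list alone; Cad 0.46 ± 0.09), of 18 erythroid genes 4 rose (4 adjusted over the list alone; Tmem56 1.55 ± 0.46), and of 9 fetal-type progenitor genes 3 rose (3 adjusted over the list alone; Dlk1 3.65 ± 0.52, Plagl1 1.66 ± 0.45). The erythroid genes had a median of -1.47 in the pair of NHD13ITDVav and ITDvav, where Tmem56 was at 0.741 against 1.30 CPM, and of 0.61 or more in the other 5 pairs. Of 64 interferon response genes 17 rose and none fell (16 adjusted over the list alone; Oas2 2.60 ± 0.39). With an estimated correlation these 4 lists had adjusted p = 0.668, 0.761, 0.5678 and 0.761. The interferon medians of single pairs were 0.99, 1.46, 0.28 and 1.07 in the 4 pairs with the receptor, and -0.65 and -0.02 in the pairs labelled Ifnar-/-.

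In all, genes changed by NUP98-HOXD13 numbered 2274 rising and 2496 falling of 16000, of which 1825 and 2035 had 1 sign in all 6 pairs. Of these calls 1567 rose with the ITD and fell with NUP98-HOXD13, and 1397 did the reverse, where independent lists would share 592.5 and 543.6. Only 77 rose and 40 fell with both, against 539.8 and 596.7. The fits share libraries, and how far the mix of cells accounts for these opposed calls was not tested. The count fell to 2150 without the pair of Flt3-ITD NUP98-HOXD13 Ifnar-/- and Flt3-ITD Ifnar-/-, to 2545 without that of NUP98-HOXD13 Ifnar+/- and to 2916 without that of NUP98-HOXD13 Ifnar-/-. Counts summed within the erythroid-like class gave 3038, but different clusters held that class in the compared libraries. Cluster 15 held 41.1% of NHD13 (48.3% erythroid-like in all) and 0.0136% of WT. In the Ifnar set cluster 1 was the largest of the class with the fusion, at 18.6% to 47.4% of cells against 4.98% to 11.6% in the partners, and cluster 7 held 0.425% to 1.32% against 7.79% to 14.1%. In 3 of the 6 pairs Xist was above 1 CPM only in the library with the fusion, and in none only in its partner.

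Within the GM-progenitor-like class, 141 of 12095 genes rose and 105 fell with NUP98-HOXD13 in 4 pairs. Prg2, the eosinophil major basic protein gene, rose 69.0-fold (log2 6.11 ± 0.75, edgeR adjusted p = 0.0011), followed by Pbx3 (3.88 ± 0.22), Bambi (1.46 ± 0.14), Slfn2 (1.46 ± 0.23) and Hoxa9 (1.45 ± 0.11). The 6 measured genes of the eosinophil list had a median of 2.50, and whether the class held eosinophil-lineage cells was not tested. The basophil protease gene Mcpt8 (-1.97 ± 0.16), Serpinf1 (-1.33 ± 0.16), Cpne2 (-1.25 ± 0.15), Slc4a8 (-1.15 ± 0.16) and the histone gene Hist1h3i (-1.13 ± 0.17) fell in 4 of 4 pairs. Interferon response genes rose in 28 of 61 cases (52 adjusted over the list alone), with adjusted p = 0.492 with an estimated correlation. Their medians were 2.20, 0.38 and 1.31 in the 3 pairs with the receptor and -0.10 in the pair labelled Ifnar-/-, where 16 of 61 were above 0. In this class 14 of 17 HOX genes and cofactors rose while 1 fell, with adjusted p = 0.0563 with an estimated correlation. Without the pair of NHD13ITDVav and ITDvav the count of changed genes was 78. In the HSC/MPP-like class no pair had 30 cells on both sides, so NUP98-HOXD13 was not tested there.

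Whether the ITD acted differently with NUP98-HOXD13 was tested as an interaction over 3 squares of 4 libraries. No gene passed in edgeR, with 768 of 16000 at an unadjusted p under 0.05 and 6 genes by DESeq2's Wald test. In simulated data with the same interaction in every square, the test called 41.8% of genes with a 2-fold interaction and 69.7% of those with a 4-fold one. Interactions that vary between squares may be called less often. The interferon list had a median interaction of 0.58 with none of its 64 members passing (0 adjusted over the list alone) and a camera adjusted p of 2.67e-07, with adjusted p = 0.476 with an estimated correlation. Its medians were 0.44, 0.65 and 0.85 in the 3 squares. The lymphoid-primed list had a median of 1.82, with adjusted p = 0.457 with an estimated correlation.

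Loss of the interferon receptor was compared in 4 pairs of Ifnar-/- against Ifnar+/- libraries. Interferon-inducible genes had the lowest values: Ifi27 fell by 3.88 ± 0.25 on the log2 scale (edgeR adjusted p = 0.00718), from 97.6 to 6.60 CPM, lower in 4 of 4 pairs. The antiviral genes Ifi44, Oas1g and Oas2 went from 6646, 1142 and 3533 counts in the Ifnar+/- libraries to 1, 0 and 8 in the Ifnar-/- libraries. Of 63 measured interferon response genes 9 fell over all genes tested, and all 63 fell adjusted over the list alone, with a median of -1.97. The camera call had adjusted p = 0.226 with an estimated correlation. Of 16 MHC class I genes 1 fell (13 adjusted over the list alone), H2-Q6 at -8.45 ± 0.80, a gene with near-identical neighbours, with adjusted p = 0.313 with an estimated correlation. Hba-a2 rose by 0.68 ± 0.05. The interferon medians of single pairs were -0.94 and -0.93 without NUP98-HOXD13 and -2.74 and -2.79 with it.

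In all, 1 gene rose and 14 fell of 15463, all with 1 sign in 4 of 4 pairs, and DESeq2's Wald test called 111. The count was 0 without the pair of Flt3-ITD NUP98-HOXD13 libraries, 6 without the pair that lacked the ITD and NUP98-HOXD13, and 27 without the pair of NUP98-HOXD13 libraries. Within the GM-progenitor-like class 21 of 10730 genes fell in 3 pairs, and the 1 that rose was the Y-linked gene Eif2s3y (0.94 ± 0.13). In 2 of the 3 pairs the Ifnar-/- library had Xist under 1 CPM and its partner had both Xist and Ddx3y. The class I genes H2-K1 (-1.70 ± 0.23) and H2-D1 (-1.74 ± 0.26) and Ifi27 (-3.54 ± 0.14) fell, and Isg15 and Ifi27l2a went from 431 and 876 counts to 1 and 0. Within the HSC/MPP-like class 30 of 11440 genes rose and 102 fell, on 2 pairs and 1 residual degree of freedom. In both pairs the Ifnar-/- library had Xist under 1 CPM (-9.90 ± 0.14 in this class) and its Ifnar+/- partner had both Xist and Ddx3y, so sex ran with the receptor label. Without Xist, Tsix and Y-linked genes the counts were 27 and 99. There 49 of 58 interferon response genes fell (53 adjusted over the list alone), with Rtp4 (-4.04 ± 0.18), Ifi27 (-3.65 ± 0.13), Iigp1 (-2.35 ± 0.17) and Oasl2 (-2.15 ± 0.14) among them and Ifi44 at 0 counts against 486. The carbonic anhydrase gene Car1 (1.33 ± 0.14), Mt1 (1.04 ± 0.18), Hist1h3c (0.89 ± 0.20), Hist1h4h (0.88 ± 0.16) and Klf9 (0.56 ± 0.15) rose. With an estimated correlation the interferon list had adjusted p = 0.522 in the GM-progenitor-like and 0.688 in the HSC/MPP-like class.

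Whether the ITD acted differently without the receptor was tested over 2 squares. No gene passed in edgeR, with 482 of 16805 at an unadjusted p under 0.05 and 5 genes by DESeq2. The interferon list had a median of -0.32 with 0 of 64 members passing (0 adjusted over the list alone), a camera adjusted p of 1.83e-09 and adjusted p = 0.802 with an estimated correlation. In simulated data with the same interaction in both squares, this test called 34.3% of genes with a 2-fold interaction and 62.1% of those with a 4-fold one.

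Loss of 1 Runx1 copy was compared in 2 pairs, with the spread taken from all 16 libraries. No gene passed in edgeR, with 691 of 16805 at an unadjusted p under 0.05 and 44 by DESeq2. Neutrophil granule and surface genes had a median of 1.96, with 6 of 11 rising adjusted over the list alone and none over all genes tested. Levels were low: Camp averaged 0.843 CPM and Ngp 0.164 over the libraries. S100a8 and S100a9 together were 0.006% of UMIs in Runx1-het, 0.003% in Flt3-ITD Runx1-het and at most 0.001% elsewhere. Whether a few cells carried this list was not tested. The list's camera test gave adjusted p = 2.32e-18, and adjusted p = 0.0676 with an estimated correlation. Its medians were 1.44 in the pair without the ITD and 2.40 in the pair with it, where Xist was at 897 CPM in Flt3-ITD Runx1-het and 0.174 in Flt3-ITD. Without the pair of NHD13ITDVav and NHD13, which enters only through the shared spread, 67 genes passed, and without that of Flt3-ITD NUP98-HOXD13 Ifnar+/- and NUP98-HOXD13 Ifnar+/- 3 did.

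The interaction of the ITD with Runx1-het rested on 1 square, in which Flt3-ITD alone had almost no Xist (0.174 CPM, against 897 to 1020 in the others), so sex ran along the interaction. The interferon-stimulated exonuclease gene Isg20 passed (log2 -1.94 ± 0.17, edgeR adjusted p = 0.044, 575 genes at an unadjusted p under 0.05, 19 genes by DESeq2). Isg20 was at 44.98 CPM in wildtype, 48.6 in Runx1-het, 44.2 in Flt3-ITD and 11.5 in Flt3-ITD Runx1-het. The interferon list had a median interaction of -0.95 with 1 of 64 members falling (3 adjusted over the list alone), a camera adjusted p of 1.03e-23 and adjusted p = 0.71 with an estimated correlation. The call of Isg20 was lost with stricter cell filters, with doublets kept, and without the pair of Flt3-ITD Ifnar+/-, Flt3-ITD Ifnar-/-, Flt3-ITD NUP98-HOXD13 Ifnar-/- or ITDvav (0 genes each). Without the pair of Flt3-ITD NUP98-HOXD13 Ifnar+/- 3 genes passed, and without that of NHD13ITDVav 174.

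Cell classes were compared as shares of each library's kept cells. Erythroid-like cells had a lower share with the ITD in 8 of 8 pairs, with a mean of 27.3% ± 19.5 (SD, n = 8) against 50.5% ± 17.6 (two-sided exact sign-flip permutation test, p = 0.00781, the smallest that 8 pairs allow, and adjusted p = 0.0703 over 9 classes). With NUP98-HOXD13, HSC/MPP-like cells averaged 0.172% ± 0.114 (SD, n = 6) against 15.1% ± 17.3 (median 9.13%), lymphoid-primed-like cells 1.76% ± 1.21 against 16.9% ± 8.51, and GM-progenitor-like cells 3.39% ± 3.50 against 7.28% ± 2.99. Each was lower in 6 of 6 pairs, with exact p = 0.0312, the smallest that 6 pairs allow, and adjusted p = 0.0938. These 3 classes leave out cells in unnamed clusters whose genes or cells follow the fusion or 1 library. Cluster 6, led by genes that changed with the fusion, held 4.66% to 31.7% of each fusion library and at most 0.0774% of any other, and cluster 9 held 66.75% of NHD13ITDVav, so the shares do not show which cell types became rarer. Likewise cluster 8, led by genes that changed with the ITD, held up to 30.6% of a library with the ITD. The HSC/MPP-like mean without the fusion was carried by ITDvav at 50.25%, nearly all of it cluster 14. Without that pair the class averaged 0.189% ± 0.119 against 8.03% ± 1.98 (SD, n = 5, exact p = 0.0625, the smallest that 5 pairs allow, adjusted p = 0.1125). No class passed after adjustment for either factor, and 1 class for the ITD and 3 for NUP98-HOXD13 were under 0.05 unadjusted. Those classes were at the smallest p their pairs allow, which did not suffice over 9 classes. The lack of calls therefore does not show that shares were unchanged. With 4 pairs the exact test cannot go below 0.125 for Ifnar-/-, where GM-progenitor-like cells were lower in 4 of 4 pairs (2.72% ± 2.06 against 3.94% ± 3.01, SD, n = 4) and HSC/MPP-like cells higher in 4 of 4 (4.79% ± 5.25 against 4.01% ± 4.74), each with exact p = 0.125 and adjusted p = 0.5625. The HSC/MPP-like share was 1 of the 9 classes tested for the ITD (higher in 6 of 8 pairs, exact p = 0.203, adjusted p = 0.305), but the genes that set cluster 14 apart include Ifitm1 and Socs2, which changed with the ITD, so no comparison is drawn from it.

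**Figure D2:**
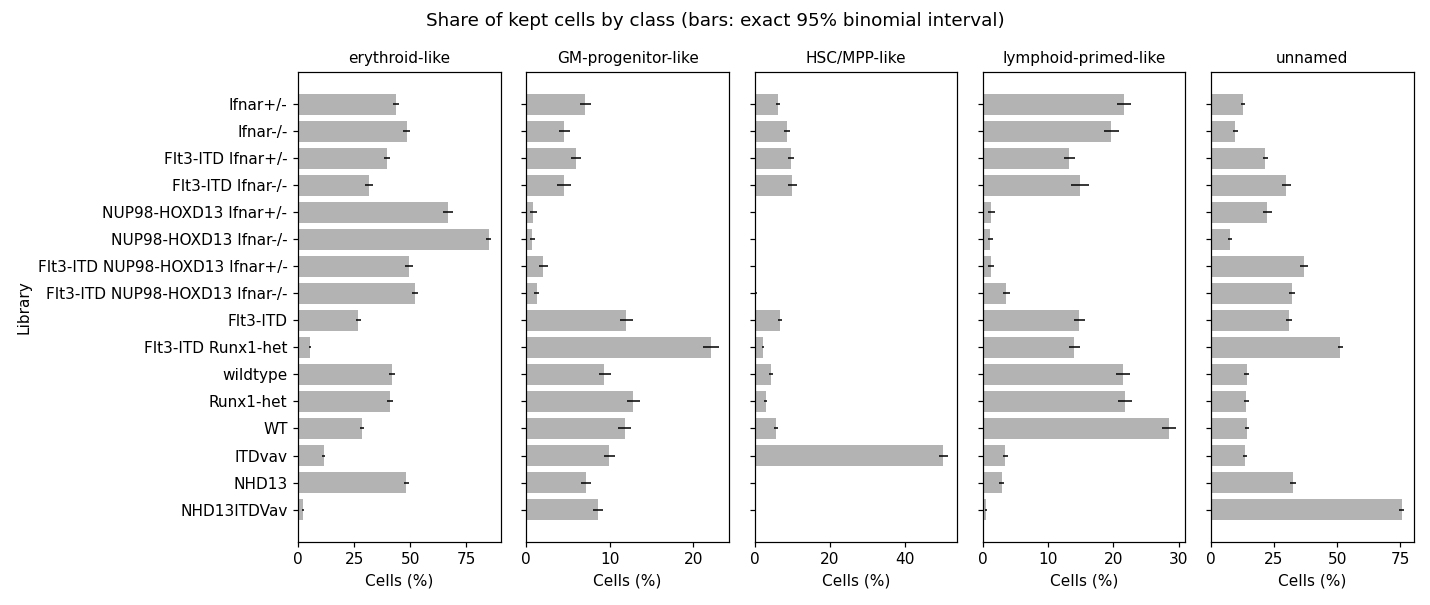
Share of kept cells (percent, horizontal axes) in 4 named classes and in unnamed clusters for each of the 16 libraries (vertical axis); whiskers are exact 95% binomial intervals, which cover counting error only. Erythroid-like cells run from 2.10% in NHD13ITDVav to 84.9% in NUP98-HOXD13 Ifnar-/-, and unnamed clusters from 7.59% in the latter to 75.5% in the former.

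The 10 antibody tags shared by all libraries gave a second readout. Among them SA_PE is named for no surface marker, and it enters the total of the shares, with 19.5% of the counts in WT. With the ITD, CD117 (the Kit receptor used in the sort) had a lower share of antibody counts in 8 of 8 pairs (15.9% against 22.6%, mean log2 difference -0.52 ± 0.24 SD, n = 8) and CD48 a higher one in 8 of 8 (69.9% against 62.8%, 0.16 ± 0.13), each with exact p = 0.00781 and adjusted p = 0.0391 over 10 antibodies. These are shares of 1 total, so a rise of the abundant CD48 lowers the others. As counts per kept cell, a scale added after the data were seen that also holds each library's antibody depth, neither passed, with 2 of the 10 antibodies at an unadjusted p under 0.05. CD117 was then lower in 7 of 8 pairs (-0.39 ± 0.38 SD, n = 8, exact p = 0.0312, adjusted p = 0.156) and CD48 higher in 5 of 8 (0.29 ± 0.40, exact p = 0.102, adjusted p = 0.254). With NUP98-HOXD13 CD117 and CD150 were higher and CD34 and CD201 lower in 6 of 6 pairs, with CD34 at -1.75 ± 0.82 (SD, n = 6), CD201 at -1.45 ± 0.41, CD150 at 1.16 ± 0.43 and CD117 at 0.66 ± 0.26, each with exact p = 0.0312 and adjusted p = 0.0781. Per kept cell CD34, CD201 and CD150 kept 1 sign in 6 of 6 pairs (adjusted p = 0.104) and CD117 was higher in 5 of 6 (adjusted p = 0.156).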

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

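Of the tests in this part, those of single-pair outliers, of cell mixture, of poor-quality cells and of whole-library shifts were set before their results were seen; the test of the receptor, the test beside HSC/MPP-like cells, the label swaps, those of sign shares included, and the NUP98-HOXD13 by Ifnar-/- interaction were chosen afterwards.

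Interferon response genes were highest in the 2 receptor-bearing libraries with both the ITD and NUP98-HOXD13, at a mean log2 CPM of 5.13 in Flt3-ITD NUP98-HOXD13 Ifnar+/- and 5.88 in NHD13ITDVav, against at most 4.62 (ITDvav) in the other receptor-bearing libraries. Within the erythroid-like, megakaryocyte-like and GM-progenitor-like classes 6 of 6 values lay above every other receptor-bearing library with 30 cells, on mean log2 CPM and on summed CPM. That met the bound set against a different mix of cell classes. However, the values came from 2 libraries, in NHD13ITDVav from 190, 207 and 775 of 9056 cells. NUP98-HOXD13 Ifnar+/-, the highest other library in erythroid-like and megakaryocyte-like cells, had 15 GM-progenitor-like cells and was left out of that class. RNA shared between the cells of a library was not tested, so a different mix stays open. Poor-quality cells are argued against, since with stricter filters the gap of 0.51 in mean log2 CPM (0.20 in log2 summed CPM) was 108% of its size. The library with both mutations and no receptor lay below the library labelled only Ifnar+/-, which keeps 1 receptor copy, by a difference of -1.64. Signalling through the receptor would give such a difference. The added NUP98-HOXD13 by Ifnar-/- test gave the list medians of -1.84 and -1.76 in its 2 squares, with 62 and 64 of 64 members below 0 and camera p = 1.14e-42 (p = 0.0439 with an estimated correlation). No single gene passed in edgeR (1987 at an unadjusted p under 0.05, 517 by DESeq2). Whether the ITD and NUP98-HOXD13 together exceed their separate effects stays open, since no gene passed that interaction, and each genotype is 1 library within a set.

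The genes changed by the ITD over all cells were weighed against a shift in the mix of cells. Of 6538 called genes tested within GM-progenitor-like cells, 85.2% had the same sign there, and of 6332 within HSC/MPP-like cells, where cluster 14 holds the ITDvav cells, 44.8% did. The class sums come from the same libraries as the all-cell sums, and by rank the real labels (84.3% and 48.4%) lay inside the range of swapped labels (71.9% to 89.7% and 45.04% to 73.8%), so the bound of 70% set beforehand was too low and a mixture change cannot be told apart from change within cells by these shares. Within erythroid-like cells, most of them cluster 15 in NHD13, 370 of 6856 had the other sign and 1463 were called again, and the share by rank was 92.5% against 71.6% to 91.8% for swapped labels, but the changes had a median of 0.459 times their all-cell size and RNA shared between the cells of a library was not tested, so mixture stays open there too. Erythroid genes, which fell over all cells by a median of -1.43 beside the lower erythroid-like share, had -0.23 within that class with 5 of 18 falling, and how much of their fall is mixture stays open.

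Cluster 9 held 6045 cells of NHD13ITDVav among its 6088, and a shift of that whole library, whether technical or through its genotype, may account for it: its 10 leading genes were higher by a median log2 difference of 3.58 or more than in NHD13 in both the GM-progenitor-like and megakaryocyte-like classes. For cluster 14 (3851 of 3879 cells from ITDvav, set against WT) the medians were 2.32 in GM-progenitor-like cells, with 10 of 10 genes above 1, and 0.61 in megakaryocyte-like cells, with 4 of 10. For cluster 15 (2725 of 2778 from NHD13, set against WT) they were 0.42 and 0.72. The test asked for at least 1 in both classes for a shift and at most 0.3 in both against one, so a library shift and a cell state cannot be told apart for these 2 clusters. For cluster 9, which held 66.75% of NHD13ITDVav, RNA shared between the cells of a library was not tested. Such RNA could raise its leading genes in the other classes, so a cell state stays open there too. Within a set a library and a genotype are 1 and the same. Flt3-ITD, counted with ITDvav as carrying the ITD but in another set, had 0.0619% of its cells in cluster 14, against 49.4% of ITDvav.

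Label swaps within backgrounds gave as many genes as the real labels in 1 of 100 draws for the ITD (7682, the highest other 4482, with 1 pair swapped), in 1 of 32 for NUP98-HOXD13 (4770, highest other 1621, with 5 pairs swapped) and in 1 of 32 for the ITD in GM-progenitor-like cells (482, highest other 11). The real labels count as 1 of the swaps here and below, and no other swap gave as many genes in these 3 fits. That argues against chance for these 3 counts, but 1 of 32 is the smallest share that 32 swaps allow. These shares were not adjusted for the number of fits. The swaps do not separate a factor from library or sex differences that ran with it. The swaps are too few for a share under 0.05 in the other fits: 4 for the ITD by NUP98-HOXD13 interaction (4 of 4 as large, real 0, highest other 0), 8 for Ifnar-/- (1 as large, real 15, highest other 0), 16 for the ITD in HSC/MPP-like cells (1 as large, real 83, highest other 0), 8 for NUP98-HOXD13 in GM-progenitor-like cells (1 as large, real 246, highest other 3) and 4 for Ifnar-/- in GM-progenitor-like cells (1 as large, real 22, highest other 2).

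Among 81 sets of pair medians, 8 had a pair far from the others, where chance gives about 1 in 20. The pair of NHD13ITDVav and ITDvav stood apart for NUP98-HOXD13 in T and NK lineage genes (4.55, nearest other -1.93), erythroid genes (-1.47, nearest 0.61), stroma and endothelium genes (-2.61, nearest -1.80), MAPK feedback genes (0.43, nearest -0.18) and fetal-type progenitor genes (2.48, nearest 0.40). The pair of NHD13 and WT stood apart in p53 target genes (0.79, nearest 0.03). For the ITD the pair of Flt3-ITD NUP98-HOXD13 Ifnar-/- and NUP98-HOXD13 Ifnar-/- stood apart in stem cell genes (1.13, nearest 0.66), and for Ifnar-/- the NUP98-HOXD13 pair in T and NK lineage genes (-0.54, nearest 0.06).

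Isg20 differed between backgrounds in its response to the ITD by the interaction with Runx1-het (log2 -1.94), in a square where Flt3-ITD alone had almost no Xist (0.174 CPM), so sex ran along it. Of antibody tags measured only in the set with WT, CD317, an antibody against the interferon-inducible protein BST2, had 32.0 counts per cell in NHD13ITDVav against 14.0 in WT, 11.01 in ITDvav and 19.1 in NHD13, and B220 had 37.0 against 14.0, 3.39 and 18.0; with 1 library each the differences were not tested.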

How the results depend on the processing

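The alternatives within the erythroid-like class, without the low-UMI clusters, without the Ifnar-/- libraries and of antibody counts per cell were chosen after the data were seen. With a pair left out at a time the genes changed by ITD were 6546 to 7272 and the genes changed by NUP98-HOXD13 2150 to 6728; Ifnar-/- gave 0 to 27, Runx1-het 0 to 67, ITD by Runx1-het 0 to 174, the ITD in HSC/MPP-like cells 20 to 289 and in GM-progenitor-like cells 129 to 333, NUP98-HOXD13 in GM-progenitor-like cells 78 to 337 and Ifnar-/- there 15 to 31. The 67 and the 174 came without NHD13ITDVav and NHD13. Isg20 lost its call without the pairs of Flt3-ITD Ifnar+/-, Flt3-ITD Ifnar-/-, Flt3-ITD NUP98-HOXD13 Ifnar-/- or ITDvav. The cause of these shifts was not tested.

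Within the erythroid-like class, which has fewer cells and tested genes, the genes changed by ITD were 1648 and the genes changed by NUP98-HOXD13 3038, with 26 for Ifnar-/-; cluster 15 was most of this class in NHD13. Without the Ifnar-/- libraries, so with fewer pairs, the ITD count was 4865. DESeq2's Wald test gave 111 genes for Ifnar-/-, 44 for Runx1-het, 19 for ITD by Runx1-het, 6 for ITD by NUP98-HOXD13 and 5 for ITD by Ifnar-/-. With no filter on low counts there were 50 for Ifnar-/- and, within classes, 540 (ITD, HSC/MPP-like), 1398 genes changed by ITD in GM-progenitor-like cells, 709 genes changed by NUP98-HOXD13 in GM-progenitor-like cells and 139 for Ifnar-/- there. ITD by Runx1-het gave 0 with stricter cell filters and 0 with doublets kept. Of surface antibody counts, 2 antibodies passed as shares and 0 as counts per cell (2 for the ITD and 3 for NUP98-HOXD13 at an unadjusted p under 0.05). Of 100 list calls 1 held with an estimated correlation; within classes 20 (HSC/MPP-like) and 28 (GM-progenitor-like) were made on fewer comparisons.

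Signs reversed, none past the threshold, within the erythroid-like class for Hmga2 (-0.11), Il1rl1 (0.077) and Cdkn1a (-0.65) with the ITD and for Gas2l3 (0.092), Kif23 (0.036), Cxcr2 (0.089) and Brip1 (0.0078) with NUP98-HOXD13. List calls reversed within HSC/MPP-like cells for stem cell (-0.56), S phase (0.12) and MYC genes (0.16) with the ITD and S phase genes (-0.11) with Ifnar-/-, and within GM-progenitor-like cells for stem cell genes (0.40) with NUP98-HOXD13 and mast and basophil genes (0.14) with Ifnar-/-. Values of named genes otherwise stayed on their side of the threshold in 2559 cases, lost it in 400 and gained it in 3. Size factors, doublets and additive factors left the ITD, NUP98-HOXD13 and Ifnar-/- counts within 1.5 times, and no class share passed at another resolution, without centring or with a pair left out. For NUP98-HOXD13 the last decides nothing, since with a pair left out the exact test cannot reach a p under 0.05. Not run: NUP98-HOXD13 in HSC/MPP-like cells (no pair with 30 cells) and leaving out a pair for Ifnar-/- there (1 pair would remain). The labels give no replicate numbers, so all pairs come from the genotype labels.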

Other observations

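The values in this part were looked up after the data were seen, and no test was set for them beforehand. Outside the comparisons above, Igf1, which encodes a growth factor, was at 58.5 CPM in NHD13ITDVav, 10.99 in Flt3-ITD NUP98-HOXD13 Ifnar+/- and 7.75 in Flt3-ITD NUP98-HOXD13 Ifnar-/-, and at 0.191 to 3.68 in the other 13 libraries. Dlk1, a surface protein of fetal progenitors, was at 48.6 CPM in NHD13 and 15.6 in NHD13ITDVav, at 2.28 to 12.96 in the 4 NUP98-HOXD13 libraries of the Ifnar set, and at 0.367 to 3.72 in the 10 without the fusion. Isg15 was at 266 CPM in NHD13ITDVav and 167 in Flt3-ITD NUP98-HOXD13 Ifnar+/-, at 49.6 in ITDvav and 38.3 in NHD13, and at 0.306, 0.303, 1.02 and 1.91 in the 4 Ifnar-/- libraries.

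Cluster 6, led by Dlk1, Pbx3, Hoxb8, Ddx4 and Lin28b, held 4.66% to 31.7% of each NUP98-HOXD13 library and at most 0.0774% of any other, but those genes changed with the fusion, so its size is not a comparison of cell types. Cluster 8, led by Ifitm1, Cox4i2, Socs2 and S100a4, held 30.6% of Flt3-ITD Runx1-het, 14.5% of Flt3-ITD, 10.7% of Flt3-ITD Ifnar-/- and 10.1% of Flt3-ITD Ifnar+/-, and at most 1.56% of any other library, with the same limit for the ITD. T/NK-lineage-like cells, cluster 18, led by Ccl5, Trbc1 and Tcf7, made up 9.15% of NHD13ITDVav and at most 0.692% of any other library, behind a lineage-negative, Kit-positive gate meant to remove them.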
